A study of Mus musculus with 12 samples.

How the data were processed

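Polyadenylated RNA sequencing libraries, made from 0.5 ug of total RNA per sample with a kit that does not mark strand, were read from 12 samples of 2 3T3 mouse embryonic fibroblast lines, wild type for p53 or p53 -/-, grown for 18 h with or without glutamine, 3 samples per group. Reads were processed with CASAVA 1.8, HISAT2 2.0.4 and Partek against mm10, per the submitters' processing notes, which give no order, no Partek version and no annotation. The deposited table holds 1 RPKM value per gene and sample for 19439 entries, none at 0 in all 12 samples, and the authors' counting rules for shared or antisense reads are not given in the sources used here. RPKM divides by gene length and by mapped reads, so it keeps no read count, and a gene with many reads lowers the values of all others. Of the entries, 26 carry names that a spreadsheet had turned into dates and 4 share a name with another entry; 18835 names are in the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, from which coordinates and opposite-strand overlaps were taken.

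The sum of RPKM was 284426 to 319735 per sample, 10306 to 10671 genes reached 1 RPKM, 3141 to 3915 were listed at 0, and the 10 highest genes held 4.69 to 7.64% of the sum. The steps between values under 0.5 RPKM put the depth at 37.7 to 46.9 M reads, but only 64.0 to 70.0% of those values were whole reads within 0.05, so read counts were not recovered and the count test planned for that case was not run. Another 1790 values lay above 0 and under 1e-6 RPKM, which whole reads cannot give. The precision of each value is therefore given as the SD over the 3 samples of its group and not as a counting interval. Within groups, samples differed by 1.12 to 1.87 times the variance that counting alone would give over 12 pairs. That is near what repeat libraries of one culture could give, so the 3 samples of a group are not shown to be independent. Pairs from different groups, 54 in all, differed by 27.67 to 226.48 times. Both ranges use reads estimated from RPKM, annotated length and the estimated depth, in genes of 1 annotated transcript. They are approximate, since true read counts were not recovered.

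Groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Values were transformed as log2(RPKM + 1), and 11461 genes with at least 1 RPKM in at least 3 of the 12 samples were tested. A limma fit (limma 3.58.1 in R 4.3.3) on the means of the 4 groups, with a mean-variance trend, gave 5 comparisons, 2 of medium within a line, 2 of line within a medium and the difference of the 2 medium responses. P-values were adjusted by Benjamini and Hochberg within a comparison, genes were called at an adjusted p under 0.05, and a 2-fold count added an absolute log2 change of at least 1. Of 27 gene lists, written from textbook pathways and markers, 614 of 647 symbols were found, 4 of them by a synonym. Some genes stand in several lists, so the list tests are not independent. The integrated stress response list shares Asns, Gpt2, Pycr1, Aldh18a1 and Psat1 with the glutamine metabolism list. It also shares Slc7a1 with the cationic amino acid transporters and Slc7a11 with the NRF2 targets. Lists with at least 5 tested members, 23 in all, were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. The lists of epithelial, blood and endothelial markers had too few tested members, and mitochondrially encoded genes were not analysed here. Slc7a3 and Trp53 also had an exact two-sided permutation test of 3 against 3 samples.

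The genes named are Trp53 and Slc7a3. In each comparison they also include the 8 with the largest rise and the 8 with the largest fall among called genes with at least 2 RPKM in the higher group and no overlap between the samples of the groups, leaving out predicted genes, small RNAs and pseudogenes. For the difference of the responses, overlap was not asked, a call in at least 1 medium comparison was, and the 2 RPKM applied to the highest of the 4 groups. Up to 4 called members with the largest change were drawn from each list that passed in that comparison and, whatever the test gave, from the lists of p53 targets, integrated stress response, cationic amino acid transporters and glutamine metabolism; at least 1 of these is named for most lists. Mdm2, Ccng1, Rn45s, the markers of other cell types and some genes set beside another comparison fall outside that rule and were chosen after their values were seen. Of 283 genes with coordinates that are named or in an added list, 64 have exon sequence under a gene on the other strand, and 9 have over 25%.

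The scripts were tested on simulated data in which 200 genes were changed. For the medium comparison in WT, limma recovered 85.1% of 67 genes changed 1.2-fold and 100% of those changed 1.5-fold or 2-fold, with 19 calls among 11261 unchanged genes, in a run on 11461 genes. For the difference of the responses it recovered 59.7% at 1.2-fold and 100% at 1.5-fold and 2-fold, with 11 such calls. The simulation changed only 200 genes, with independent noise, while 90.1% of tested genes were called in the real WT comparison. With so many calls the adjustment admits larger raw p-values, so neither these recoveries nor these rates of false calls carry over to the real data. The alternatives were a pseudocount of 0.1, no filter, a stricter filter of a mean of 2 RPKM, quantile normalization, rescaling each sample to one sum, median centring, robust variances, fits on the 2 groups compared alone, the replicate number as a block, an estimated correlation for the lists, and leaving out each sample in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled tables and figures.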

Results

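RNA was sequenced from 2 lines of 3T3 mouse embryonic fibroblasts (MEFs), cells that have become immortal through repeated passage in culture. One line carried wild-type p53 (WT) and the other was described as p53 -/- (p53-null). p53, encoded by Trp53, is a transcription factor that responds to DNA damage and to metabolic stress. Each line was cultured for 18 h in Dulbecco's modified Eagle's medium (DMEM) with 2 mM glutamine (complete) or without glutamine (glutamine-free), and each of the 4 groups held 3 libraries, 12 in all. The deposited values were reads scaled to transcript length and to the mapped reads of the library (RPKM) for 19439 gene entries, of which 11461 passed a filter on low values and were tested. Values below are mean RPKM ± SD over the 3 libraries of a group (n = 3), log2 changes are on the log2(RPKM + 1) scale with their standard error (SE), and p-values are from limma unless another test is named. That scale understates the change of genes near or under 1 RPKM. Camera p-values are given at the preset correlation and, where a call did not hold, also with an estimated one. No read totals were given, and the steps between the lowest values put the depth at about 37.7 to 46.9 M reads per library. Libraries of a group correlated across genes at r = 0.998 to 0.999 over 12 pairs, as a description, since genes are not independent replicates. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. With 1 line per genotype, every difference between genotypes below is a difference between these 2 lines.

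Trp53, the gene named in the genotype labels, lies on chromosome 11 at 69580359 to 69591873 (plus strand, mm10) and was lower in each p53-null library than in each WT library. In complete medium it was 58.7, 57.8 and 59.0 RPKM in the 3 WT libraries and 27.9, 29.0 and 29.6 RPKM in the 3 p53-null libraries. In glutamine-free medium it was 109.4, 112 and 113.9 RPKM in WT and 34.0, 34.6 and 35.2 RPKM in p53-null libraries. The log2 difference, p53-null minus WT, was -1.0 ± 0.022 (SE) in complete and -1.66 ± 0.022 in glutamine-free medium (adjusted p = 8.3e-14 and 7.4e-16). A value per gene does not show which exons were read, so the transcript left in the p53-null line checks no part of the allele. Cdkn1a, the cell cycle inhibitor that is a standard p53 target (chromosome 17, 29090976 to 29100727, plus strand), was 0.973 ± 0.242 against 2.62 ± 0.328 RPKM in p53-null against WT cells in complete medium and 1.84 ± 0.164 against 16.1 ± 0.261 RPKM in glutamine-free medium. Mdm2, another p53 target, which encodes the ubiquitin ligase that degrades p53, went the other way, at 15.9 ± 0.322 against 9.79 ± 0.278 RPKM in complete medium.

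The series title puts Slc7a3, a cationic amino acid transporter that takes up arginine, at the centre of the adaptation to glutamine deprivation, and the design asks whether its response depends on p53. Slc7a3, a protein-coding gene on the minus strand of chromosome X at 101079210 to 101086020, rose in WT cells on withdrawal from 0.262 ± 0.0676 to 6.63 ± 0.412 RPKM, 25.3-fold in mean RPKM, a log2 change of 2.60 ± 0.061 (SE, adjusted p = 1.1e-13). In p53-null cells it fell from 1.06 ± 0.140 to 0.459 ± 0.0730 RPKM, a log2 change of -0.50 ± 0.061 (adjusted p = 5.6e-06). The difference of the 2 responses was 3.09 ± 0.086 on the log2 scale (adjusted p = 2.2e-12), and 5.29 with a pseudocount of 0.1. The 3 WT glutamine-free libraries held 6.19, 6.70 and 7.01 RPKM and no other library exceeded 1.17 RPKM. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 for each medium comparison within a genotype, the smallest p that design allows. In complete medium Slc7a3 was higher in the p53-null line, by a log2 difference of 0.71 ± 0.061 (adjusted p = 1.1e-07).

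**Figure D1:**
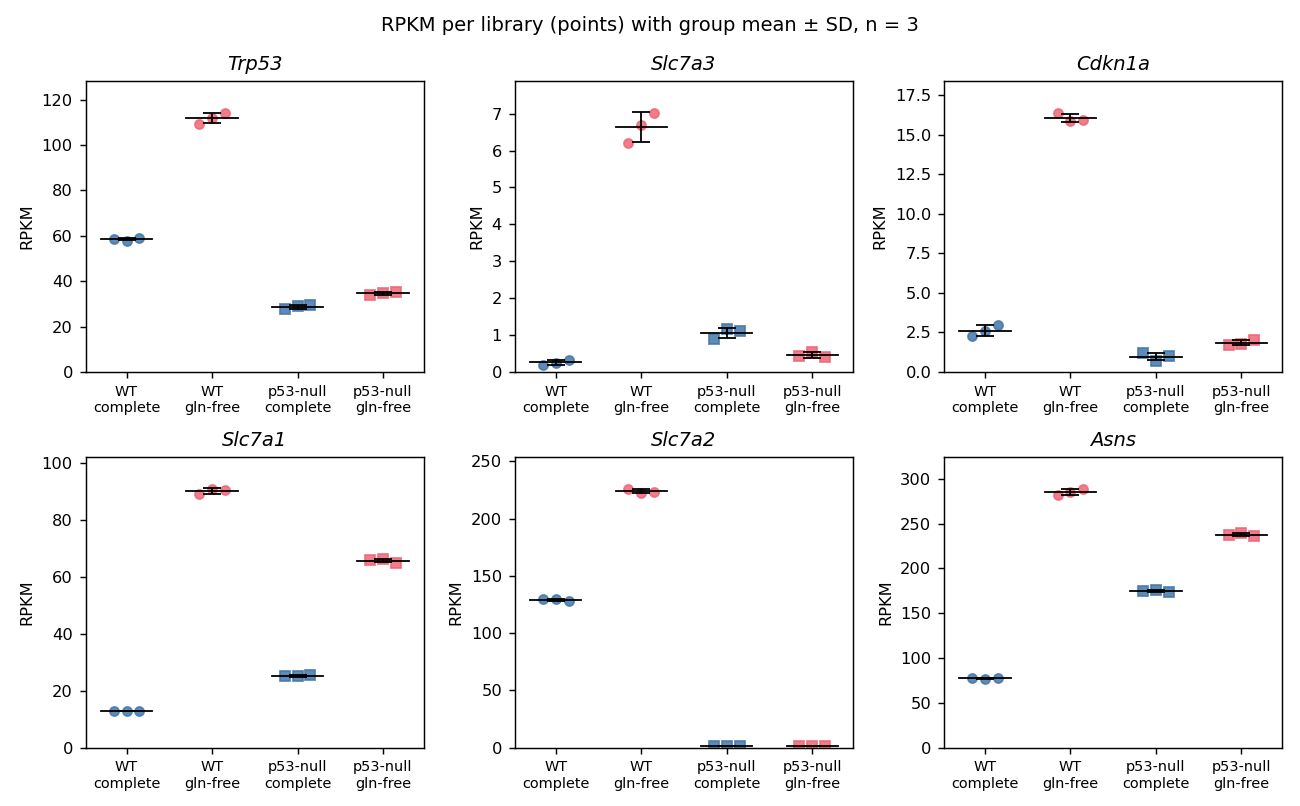
RPKM of 6 genes in each of the 12 libraries, 3 per group, on a linear axis that starts at 0; points are libraries and horizontal lines with bars are group means ± SD. Slc7a3 was highest in the 3 WT glutamine-free libraries (6.19 to 7.01 RPKM), Trp53 was lower in every p53-null library, and Slc7a2 averaged 1.62 RPKM or less in both p53-null groups.

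Withdrawal of glutamine from WT cells raised the genes of the integrated stress response, the programme that the transcription factor ATF4 drives when amino acids run short, and lowered genes of the extracellular matrix, of mitosis, of cholesterol synthesis and of the interferon response. All 35 tested members of the integrated stress response list rose, with a median log2 change of 2.08 (camera adjusted p = 5.21e-12). Among them Trib3, a pseudokinase induced by ATF4, went from 4.69 ± 0.618 to 110 ± 2.44 RPKM, the transcription factor gene Atf3 from 1.61 ± 0.0609 to 45.0 ± 0.864 RPKM, and Ppp1r15a, whose product directs a phosphatase to eIF2α, from 4.92 ± 0.0951 to 92.5 ± 0.168 RPKM. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, rose in 17 of 20 members and fell in 2 (camera adjusted p = 9.37e-05, and 0.052 with an estimated correlation). Wars went from 11.5 ± 0.311 to 67.6 ± 1.17 RPKM and Tars from 51.9 ± 1.05 to 230 ± 2.08 RPKM. All 5 tested arginine and cationic amino acid transporters rose (camera adjusted p = 0.0211, and 0.12 with an estimated correlation). Of these Slc7a1, the widely expressed arginine transporter, went from 12.8 ± 0.0761 to 90.1 ± 0.980 RPKM and Slc7a2 from 129 ± 0.678 to 224 ± 1.70 RPKM, both to higher levels than Slc7a3. Nucleotide synthesis genes rose in 19 of 24 and fell in 4, with a rise of Umps from 15.7 ± 0.0770 to 38.1 ± 0.950 RPKM, while the CTP synthase gene Ctps2 fell from 14.9 ± 0.361 to 4.35 ± 0.254 RPKM (camera adjusted p = 0.00705, and 0.18 with an estimated correlation). DNA replication genes rose in 28 of 32 members and fell in 3 (camera adjusted p = 2.2e-04, and 0.064 with an estimated correlation). E2f2 went from 3.22 ± 0.0735 to 11.8 ± 0.229 RPKM and the licensing factor gene Cdc6 from 4.92 ± 0.152 to 12 ± 0.313 RPKM.

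All 30 mitotic genes fell in WT cells, with a median log2 change of -1.49 (camera adjusted p = 6.52e-11), among them the cyclin gene Ccnb2 from 66.8 ± 1.46 to 6.94 ± 0.273 RPKM and the kinase gene Plk1 from 33.3 ± 0.531 to 5.97 ± 0.160 RPKM. All 24 tested cholesterol synthesis genes fell, median log2 change -2.03 (camera adjusted p = 2.27e-09). Fdps, an enzyme of the mevalonate pathway, went from 207 ± 1.11 to 25.2 ± 0.380 RPKM. Of 32 extracellular matrix and fibroblast genes 31 fell and 1 rose, median log2 change -2.24 (camera adjusted p = 6.52e-11). The collagen gene Col1a1 went from 240 ± 2.12 to 11 ± 0.406 RPKM, Col6a3 from 43.4 ± 0.391 to 2.94 ± 0.0835 RPKM and the matrix protein gene Thbs1 from 88.7 ± 0.814 to 4.75 ± 0.0465 RPKM. Beside the matrix genes, some markers of other cell types moved in the same libraries: the neuronal gene Stmn2 went from 23.5 ± 0.883 to 2.66 ± 0.172 RPKM and Cd74, which encodes the invariant chain of MHC class II, from 1.15 ± 0.187 to 14.8 ± 1.11 RPKM. Of 6 tested muscle and neural markers 4 fell and 1 rose, the neuronal gene Tubb3, from 13.45 ± 0.565 to 16.49 ± 0.255 RPKM (camera adjusted p = 0.26 for the list). All 20 tested interferon response genes fell, median log2 change -1.18, and -2.49 with a pseudocount of 0.1 and -1.92 with libraries rescaled to one sum (camera adjusted p = 1.44e-06). Ifit1 went from 9.10 ± 0.348 to 0.215 ± 0.0568 RPKM and Isg15 from 7.49 ± 0.173 to 0.403 ± 0.0758 RPKM. Of 18 glycolysis genes 16 fell and 1 rose (camera adjusted p = 4.19e-04). Tpi1 went from 367 ± 2.82 to 108 ± 1.09 RPKM and Pfkm from 33.4 ± 0.393 to 8.56 ± 0.0794 RPKM. Most replication-dependent histone mRNAs lack a poly(A) tail, so their level can reflect RNA selection. It can also follow the share of cells that replicate DNA, and these 2 readings were not told apart. Of 9 such genes 8 fell and 9 did when adjusted over the list alone (camera adjusted p = 0.0313, and 0.09 with an estimated correlation). Rn45s, the ribosomal RNA precursor, which also lacks that tail, went from 5371 ± 338 to 3931 ± 144 RPKM in the same libraries. With quantile normalization its log2 change became 0. The p53 target list went both ways, 21 up and 15 down of 37 (camera adjusted p = 0.596). Cdkn1a rose from 2.62 ± 0.328 to 16.1 ± 0.261 RPKM, while Sesn1 fell from 17.2 ± 0.380 to 2.75 ± 0.106 RPKM and Psrc1 from 11.7 ± 0.571 to 1.09 ± 0.134 RPKM. The enzymes of glutamine and glutamate metabolism also went both ways, 13 up and 8 down of 23 (camera adjusted p = 0.359). Pycr1, which makes proline, went from 6.26 ± 0.229 to 38.0 ± 0.595 RPKM, Gpt2 from 21.1 ± 0.159 to 108 ± 2.08 RPKM and Idh1, down, from 33.7 ± 0.336 to 6.0 ± 0.248 RPKM. Pycr1 and Gpt2 are also in the integrated stress response list.

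By size of change alone, the 8 largest rises in WT cells were of Car6, Avil, Cdsn, Trib3, Atf3, Ppp1r15a, Angptl6 and Fosl1. Car6, which encodes a secreted carbonic anhydrase, went from 0.211 ± 0.0638 to 89.0 ± 0.974 RPKM (log2 change 6.22 ± 0.048), Avil, which encodes the actin-binding protein advillin, from 0.161 ± 0.0587 to 70.0 ± 0.511 RPKM, the corneodesmosin gene Cdsn from 3.33 ± 0.109 to 103 ± 4.10 RPKM and Angptl6 from 1.36 ± 0.107 to 35.9 ± 0.695 RPKM. Fosl1, of the AP-1 transcription factor family, went from 3.39 ± 0.522 to 62.9 ± 0.572 RPKM, of which a part could be read from Ccdc85b, since 62.4% of its exon length lies under that gene on the other strand and the library kit does not mark strand. The 8 largest falls were of Mgp (matrix Gla protein, 61.1 to 1.5 RPKM), Cbr2 (59.9 to 1.73), Olfml3 (26.8 to 0.371), Col1a1, the glutathione transferase gene Gstt1 (67.1 to 2.52), Col11a1 (25.4 to 0.426), Steap4 (32.1 to 0.790) and Prelp (27.2 to 0.567). In all, 10321 of 11461 genes passed an adjusted p of 0.05 in WT cells, 5276 higher and 5045 lower without glutamine, and without the filter 6023 higher and 6311 lower. Of these 2594 changed at least 2-fold on the log2(RPKM + 1) scale, 1117 up and 1477 down, and the median log2 change of all genes was 0.01. With the small spread between libraries most genes pass, so the size of a change carries more than its p. With an estimated correlation the calls of the integrated stress response, mitotic, cholesterol synthesis, extracellular matrix, interferon response and glycolysis lists held. Adjusted over the list alone, the counts were those given over all genes for each tested list in each comparison, except the histone genes here and the interferon response genes in p53-null cells (3 up and 10 down).

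In p53-null cells glutamine withdrawal moved many of the same groups by smaller amounts, and also some groups that did not pass in WT cells. The integrated stress response genes rose in 33 of 35, with a median log2 change of 0.47 (camera adjusted p = 3.3e-07). Nupr1, a stress-induced chromatin protein gene, went from 19.8 ± 1.10 to 81.6 ± 0.252 RPKM, Atf3 from 5.94 ± 0.165 to 23.4 ± 0.288 RPKM, Ppp1r15a from 17.5 ± 0.310 to 71.3 ± 1.92 RPKM and Slc7a1 from 25.2 ± 0.272 to 65.7 ± 0.618 RPKM. The aminoacyl-tRNA synthetases rose in 16 of 20 and fell in 3 (camera adjusted p = 0.0121, and 0.17 with an estimated correlation). Nars went from 167 ± 0.840 to 253 ± 2.09 RPKM. Of the 5 cationic amino acid transporters 3 rose and 2 fell (camera adjusted p = 0.712). Slc7a6 went from 24.2 ± 0.123 to 31.1 ± 0.428 RPKM, and Slc7a3 was among those that fell. Endoplasmic reticulum chaperone genes rose in 16 of 19 (camera adjusted p = 0.00314), while in WT cells 8 rose and 10 fell (camera adjusted p = 0.87). The main chaperone gene of that compartment, Hspa5, went from 201 ± 1.10 to 363 ± 2.51 RPKM and Dnajb9 from 4.75 ± 0.25 to 12.1 ± 0.394 RPKM. Immediate early genes, which respond to growth signals, rose in 14 of 17, median log2 change 1.04 (camera adjusted p = 0.00302, and 0.14 with an estimated correlation). In WT cells 9 of them rose and 7 fell, median 0.12 (camera adjusted p = 0.63). Myc went from 37 ± 1.17 to 113 ± 1.11 RPKM, Maff from 3.64 ± 0.325 to 12.8 ± 0.396 RPKM and Egr1 from 2.91 ± 0.0245 to 9.35 ± 0.279 RPKM. DNA replication genes rose in 29 of 32 (camera adjusted p = 3.58e-05). Mcm10 went from 22.9 ± 0.243 to 48.0 ± 0.670 RPKM and Prim1 from 50.2 ± 1.03 to 84.2 ± 1.28 RPKM.

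Matrix genes fell in 24 of 32 and rose in 7 in p53-null cells, median log2 change -0.74 (camera adjusted p = 2.68e-07), with the smooth muscle actin gene Acta2 from 106 ± 0.928 to 11.7 ± 0.417 RPKM, decorin (Dcn) from 18.0 ± 0.519 to 3.60 ± 0.375 RPKM and lysyl oxidase (Lox) from 15.1 ± 0.168 to 4.01 ± 0.0936 RPKM. Beside them the macrophage marker Cd68 went from 7.06 ± 0.382 to 2.16 ± 0.236 RPKM and the keratin gene Krt19 from 17.5 ± 0.404 to 7.92 ± 0.222 RPKM. The blood cell markers Lyz2 and Laptm5 averaged 0.0221 ± 0.00173 and 0.0384 ± 0.00673 RPKM in p53-null cells in complete medium. Cd68 by itself therefore does not show macrophages there. Mitotic genes fell in 23 of 30 and rose in 4 (camera adjusted p = 3.3e-07). Ccnb2 went from 26.5 ± 0.860 to 12.2 ± 0.539 RPKM and Cdc20 from 26.3 ± 0.396 to 13.1 ± 0.182 RPKM. Cholesterol synthesis genes fell in 19 of 24 (camera adjusted p = 3.24e-06), with Insig1 from 10.9 ± 0.371 to 4.23 ± 0.215 RPKM, and glycolysis genes in 15 of 18 (camera adjusted p = 3.58e-05). Aldoa went from 248 ± 1.86 to 156 ± 2.62 RPKM. Interferon response genes fell in 11 of 20 (camera adjusted p = 0.00984, and 0.095 with an estimated correlation). Stat2 went from 6.37 ± 0.188 to 3.52 ± 0.137 RPKM. Tricarboxylic acid cycle genes fell in 14 of 20 (camera adjusted p = 0.00445, and 0.22 with an estimated correlation). In WT cells 12 of these fell and 8 rose (camera adjusted p = 0.448). Idh3g went from 61.4 ± 0.523 to 37.4 ± 0.496 RPKM. Targets of NRF2, the regulator of antioxidant genes, fell in 14 of 20 (camera adjusted p = 0.0024, and 0.17 with an estimated correlation). In WT cells 11 of these rose and 7 fell (camera adjusted p = 0.44). Gstm1 went from 18.3 ± 0.735 to 6.66 ± 0.627 RPKM and Nqo1 from 4.95 ± 0.177 to 1.66 ± 0.153 RPKM. The replication-dependent histone genes fell in 6 of 9 (camera adjusted p = 0.0182, and 0.085 with an estimated correlation). Hist1h2bc went from 5.09 ± 0.527 to 0.834 ± 0.115 RPKM, and Rn45s from 3137 ± 135 to 2291 ± 387 RPKM. With quantile normalization the log2 change of Rn45s turned to 0.127. Ribosomal protein genes fell in 26 of 36, median log2 change -0.18, a median that became 0.06 under quantile normalization (camera adjusted p = 3.24e-06, and 0.29 with an estimated correlation). In WT cells 19 of these rose and 12 fell (camera adjusted p = 0.322). Ribosomal protein and histone genes have many copies, so their reads may be shared with near-identical sequences. The p53 targets went both ways, 18 up and 14 down of 37 (camera adjusted p = 0.818), with median and mean log2 changes of 0.10 and 0.03, a median of -0.01 with median centring and a test directed down. Plk2 rose from 52.8 ± 0.729 to 101 ± 2.12 RPKM and Dcxr fell from 3.04 ± 0.375 to 0.995 ± 0.104 RPKM. Genes of glutamine and glutamate metabolism were also divided, 11 up and 10 down of 23 (camera adjusted p = 0.561). Idh1 fell from 15.8 ± 0.197 to 3.06 ± 0.135 RPKM.

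The 8 largest rises in p53-null cells included 3 noncoding host genes of small nucleolar RNAs, Snhg1 (55.6 ± 0.391 to 291 ± 5.04 RPKM), Zfas1 (32.7 ± 0.848 to 147 ± 2.76 RPKM) and Snhg12 (17.0 ± 0.769 to 70.1 ± 0.820 RPKM). The other 5 were Fosl1 (8.02 ± 0.605 to 57.5 ± 2.39 RPKM, with the same overlap with Ccdc85b), Txnip, which binds thioredoxin and restrains glucose uptake (16.9 ± 0.561 to 77.8 ± 0.767 RPKM), Plcxd2 (1.29 ± 0.0858 to 8.91 ± 0.26 RPKM), the growth arrest gene Gadd45a (18.4 ± 0.934 to 78.7 ± 1.27 RPKM) and Nupr1. The 8 largest falls were of the growth factor gene Ptn (38.6 to 2.54 RPKM), Anxa8 (63.0 to 5.62), Cxcl15 (8.01 to 0.0645), Acta2, Tspan8 (29.6 to 2.71), Gsta1 (19.7 to 1.62), the chemokine gene Ccl2 (13.8 to 1.42) and Gsta4 (114 to 18.0). Gsta1 has close paralogues with which it may share reads. In all, 9403 genes passed in p53-null cells, 5732 higher and 3671 lower, so 61% of the calls were higher, against 47.6% after median centring, which moved the median of all genes from 0.08 to -0.02. Of these 379 changed at least 2-fold, 146 up and 233 down, which is 38.5% up, against 27.8% with quantile normalization and 23.2% with median centring. That count was 745 with a pseudocount of 0.1 and 609 with the libraries rescaled to one sum. With an estimated correlation the calls of the integrated stress response, endoplasmic reticulum chaperone, DNA replication, extracellular matrix, mitotic, cholesterol synthesis and glycolysis lists held.

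**Figure D2:**
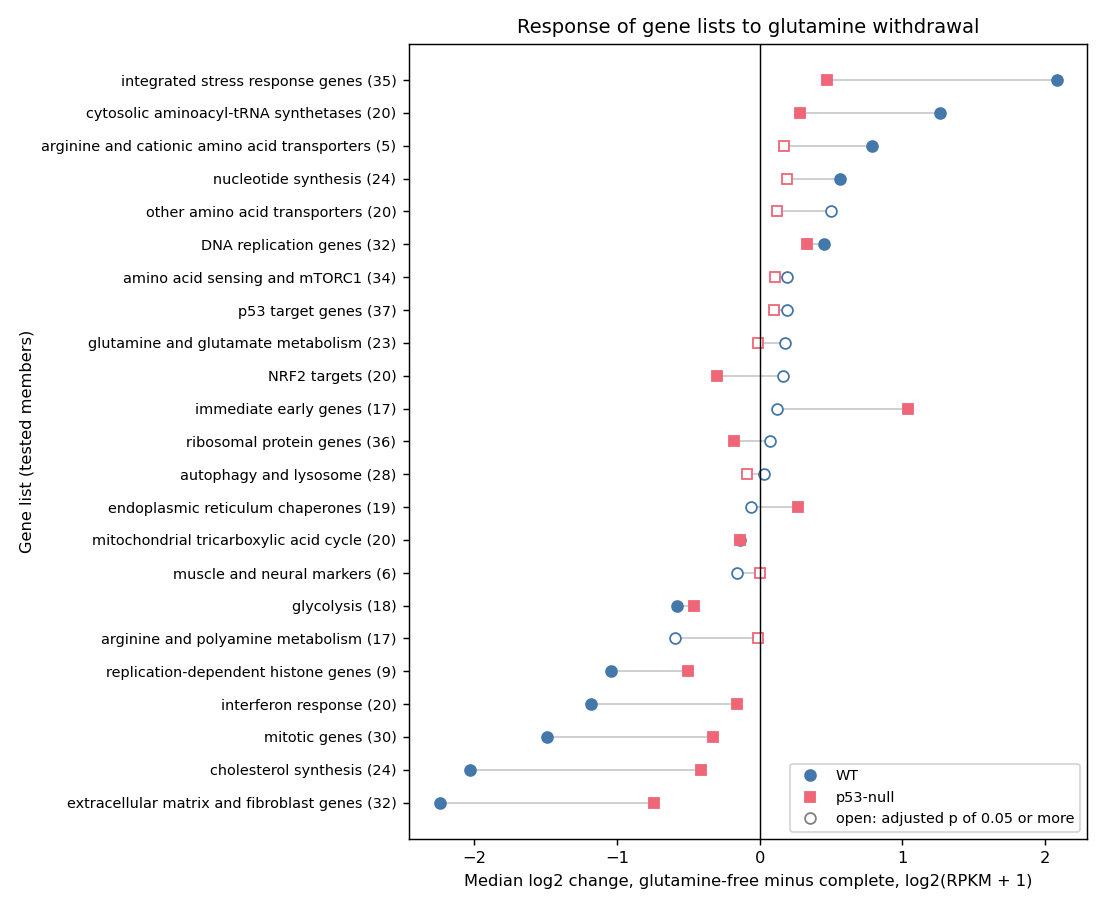
Median log2 change (glutamine-free minus complete, on log2(RPKM + 1)) of the tested members of 23 gene lists, as circles for WT and squares for p53-null cells, with filled markers where the camera adjusted p was under 0.05 and the number of tested members beside each name. The integrated stress response list had medians of 2.08 in WT and 0.47 in p53-null cells, and the extracellular matrix list -2.24 and -0.74. The sign of the p53-null median changed with a scaling for the ribosomal protein, p53 target, glutamine and glutamate metabolism, mTORC1 and muscle and neural lists, and of the WT median for the autophagy list.

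The design also asks directly whether the response to withdrawal differed between the lines, as the WT response minus the p53-null response, so that a positive value means a larger rise or a smaller fall in WT. The integrated stress response rose more in WT cells in 33 of 35 members, median difference 1.49 (camera adjusted p = 1.57e-13). Trib3 differed by 3.23 ± 0.077, Atf5 by 3.11 ± 0.034, and Cth, which makes cysteine, by 3.01 ± 0.059 (log2 ± SE, adjusted p = 5.8e-13, 8.6e-16 and 1.1e-13). All 5 cationic amino acid transporters had the larger change in WT (camera adjusted p = 0.0203, and 0.16 with an estimated correlation). Slc7a1, also in the integrated stress response list, was at 1.37 and Slc7a2 at 0.88. The aminoacyl-tRNA synthetases were above 0 in 16 of 20 (camera adjusted p = 5.95e-06). Wars was at 2.07. Glutamine and glutamate metabolism genes were above 0 in 15 of 23 (camera adjusted p = 0.0203, and 0.25 with an estimated correlation). Pycr1 was at 2.15 and the asparagine synthetase gene Asns at 1.42, both also in the integrated stress response list. Nucleotide synthesis genes were above 0 in 15 of 24 (camera adjusted p = 0.0269, and 0.25 with an estimated correlation). Nme1 was at 1.30. NRF2 targets were above 0 in 14 of 20 (camera adjusted p = 0.00432, and 0.22 with an estimated correlation). The cystine transporter gene Slc7a11, also in the integrated stress response list, was at 2.06 and Hmox1 at 2.00. Ribosomal protein genes were above 0 in 31 of 36, by a median of 0.29 and of 0.04 with quantile normalization (camera adjusted p = 5.95e-06, and 0.3 with an estimated correlation).

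All 30 mitotic genes had the more negative change in WT cells, median difference -1.05 (camera adjusted p = 4.07e-10). Cenpf was at -2.17 and Ccnb2 at -2.03. The same held for all 24 cholesterol synthesis genes, median -1.44 (camera adjusted p = 1.52e-08), with Mvd at -2.75 and Fdps at -2.49, and all 20 interferon response genes, median -1.12, and -2.00 with a pseudocount of 0.1 and -1.64 with libraries rescaled to one sum (camera adjusted p = 5.6e-06). Ifit1 was at -2.65. Of 32 matrix genes 28 were below 0, median -1.71 (camera adjusted p = 1.71e-07). Col1a1 was at -3.63 and Thbs1 at -3.08. Beside them, markers of other cell types differed too, Stmn2 at -2.74, Cd74 at 2.37, Cd68 at 1.07 and Krt19 at 0.95. Glycolysis genes were below 0 in 14 of 18 (camera adjusted p = 0.0414, and 0.21 with an estimated correlation). Tpi1 was at -1.27, while Hk2 stood above 0 at 1.05. The p53 target list was divided, 20 above and 14 below 0 of 37 (camera adjusted p = 0.388). Cdkn1a was at 1.71 and Sesn1 at -1.80. Trp53 itself rose more in WT, by 0.67 ± 0.032 (SE, adjusted p = 3.9e-10).

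The 8 genes with the largest positive difference were Car6 (6.01), Avil (5.80), Cdsn (4.32), Angptl6 (3.78), Trib3, Cox6a2 (3.20), Atf5 and the integrin gene Itgb7 (3.10). All 8 stood higher in p53-null than in WT cells in complete medium, among them Car6 at 9.39 ± 0.571 against 0.211 ± 0.0638 RPKM and Cdsn at 51.4 ± 1.64 against 3.33 ± 0.109 RPKM. The 8 with the largest negative difference were Gstt1 (-4.22), Steap4 (-4.20), Galnt15 (-3.75), Ccdc80 (-3.70), the nitric oxide synthase gene Nos2 (-3.68), Col1a1, Fabp4 (-3.63) and Ang2 (-3.58). Of these 8, Gstt1, Steap4, Galnt15, Nos2 and Fabp4 averaged under 0.1 RPKM in both p53-null groups and Ang2 was listed at 0 there, so these values rest on the fall in WT cells. In all, 9727 genes differed between the responses, 4404 above and 5323 below 0, but 5130 above and 4611 below with quantile normalization and 5151 above and 4617 below with median centring. The median over all genes was -0.06 and became 0.04 with either. Of the genes that differed, 1783 did so at least 2-fold, 35.8% of them above 0, against 45.9% with median centring. Across the tested genes the least-squares slope of the p53-null on the WT response was 0.286. Pearson r was 0.571 and Spearman rho 0.586 across genes, which are not independent replicates. Such a slope mixes the size of the response with the agreement between the lines, so it is not a ratio of sizes. The median absolute log2 change of called genes was 0.581 in WT and 0.329 in p53-null cells. Of the genes called in both lines 3946 were higher in both and 2638 lower in both, against 2639 and 1616 for independent lists, and 2006 went opposite ways. At 2-fold, 84 were higher in both, 128 lower in both and 5 opposite, against 14.2 and 30 for independent lists of calls higher or lower in both. With an estimated correlation the calls of the integrated stress response, aminoacyl-tRNA synthetase, mitotic, cholesterol synthesis, extracellular matrix and interferon response lists held.

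**Figure D3:**
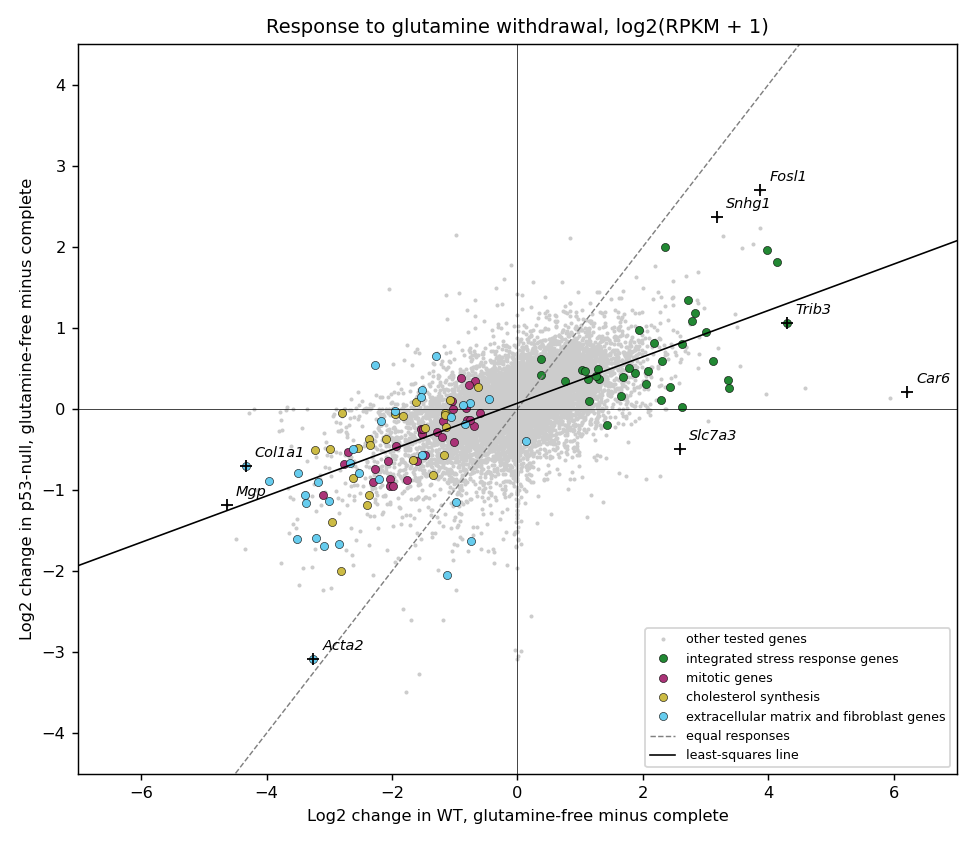
Log2 change on glutamine withdrawal (log2(RPKM + 1) scale) of 11461 tested genes in p53-null cells against that in WT cells, one grey point per gene, with the members of 4 lists in colour and 8 named genes marked. The solid line is the least-squares line, with a slope of 0.286, and the dashed line marks equal responses. Slc7a3 lies at 2.60 in WT and -0.50 in p53-null cells.

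In complete medium the p53-null cells expressed the imprinted gene Peg3 at 128 ± 0.980 against 0.216 ± 0.0394 RPKM in WT, the mesothelial surface protein gene Msln at 149 ± 0.75 against 2.30 ± 0.0780 RPKM and the matrix gene Efemp1 at 79.0 ± 0.710 against 0.00801 RPKM. WT cells expressed Enpp2, which encodes the secreted lysophospholipase autotaxin, at 483 ± 2.78 RPKM against 0.361 ± 0.0389 in p53-null cells, and the inflammatory genes Cxcl5 (198 ± 7.86 against 0.0612 ± 0.0101), Cxcl1 (171 ± 0.915 against 1.02 ± 0.153), Ptx3 (392 ± 2.54 against 2.01 ± 0.0653) and C3 (120 ± 0.207 against 0.576 ± 0.0325). The 8 most raised in p53-null cells were completed by the keratin gene Krt18 (59.6 ± 0.665 RPKM, listed at 0 in the 3 WT libraries), Gsta4 (114 ± 0.684 against 2.00 ± 0.105), Gas6 (41.8 ± 0.528 against 0.117 ± 0.0269), Renbp (36.4 ± 1.44 against 0.0461 ± 0.0258) and Tspan8 (29.6 ± 0.657, listed at 0 in WT). The 8 most lowered were completed by ceruloplasmin (Cp, 1.27 ± 0.0571 against 225 ± 1.84 RPKM), Sod3 (0.525 ± 0.106 against 134 ± 0.215) and Serpine2 (0.0231 ± 0.0243 against 71.1 ± 0.895). Cholesterol synthesis genes were lower in p53-null cells in 23 of 24, median log2 difference -1.85 (camera adjusted p = 8.58e-08, and 0.068 with an estimated correlation). Idi1 was at 14.6 ± 0.347 against 132 ± 2.15 RPKM and Hmgcs1 at 20.8 ± 0.803 against 158 ± 2.33 RPKM. Integrated stress response genes were higher in 28 and lower in 7 of 35 (camera adjusted p = 0.00109, and 0.2 with an estimated correlation). Trib3 was at 45.1 ± 0.599 against 4.69 ± 0.618 RPKM and Atf5 at 65.3 ± 0.281 against 8.12 ± 0.317 RPKM, while Ddit4 was lower at 3.19 ± 0.235 against 24.2 ± 0.307 RPKM. Aminoacyl-tRNA synthetases were higher in 15 of 20 (camera adjusted p = 0.0175, and 0.24 with an estimated correlation). Rars was at 153 ± 0.895 against 42.7 ± 0.859 RPKM.

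Matrix genes were lower in 23 and higher in 9 of 32 (camera adjusted p = 0.00214, and 0.1 with an estimated correlation). S100a4 was at 19.3 ± 1.74 against 945 ± 14.1 RPKM and Col1a2 at 29.5 ± 0.619 against 712 ± 1.42 RPKM. Markers of other cell types differed between the same libraries. Besides Krt18 and Msln, Krt19 was at 17.5 ± 0.404 against 0.110 ± 0.0341 RPKM in p53-null against WT cells and the mesothelial transcription factor gene Wt1 at 7.65 ± 0.149 RPKM and listed at 0 in WT, while the neural genes Sox2 and Stmn2 were at 6.11 ± 0.251 and 23.5 ± 0.883 RPKM in WT and listed at 0 in p53-null libraries. The sums of RPKM over all genes also stood apart, at 313165 to 314793 in the 3 WT libraries and 290973 to 292236 in the 3 p53-null libraries. Interferon response genes were lower in 18 of 20 (camera adjusted p = 3.58e-04, and 0.068 with an estimated correlation). Ddx58 was at 2.40 ± 0.131 against 19.8 ± 0.256 RPKM. Glycolysis genes were lower in 15 of 18 (camera adjusted p = 0.00109, and 0.097 with an estimated correlation). Ldha was at 127 ± 1.18 against 316 ± 4.40 RPKM and Pdk1 at 5.52 ± 0.121 against 22.4 ± 0.178 RPKM. Mitotic genes were lower in 23 of 30 (camera adjusted p = 0.0027, and 0.1 with an estimated correlation). Cdc20 was at 26.3 ± 0.396 against 87.2 ± 1.83 RPKM. Immediate early genes were lower in 11 of 17 (camera adjusted p = 0.0372, and 0.32 with an estimated correlation). Junb was at 9.39 ± 0.660 against 67.4 ± 1.51 RPKM. Histone genes were lower in 8 of 9 (camera adjusted p = 0.0143, and 0.1 with an estimated correlation). Hist1h1c was at 1.35 ± 0.109 against 9.79 ± 0.599 RPKM, and Rn45s at 3137 ± 135 against 5371 ± 338 RPKM. Ribosomal protein genes were lower in 24 and higher in 11 of 36, median -0.19, and 0.02 with quantile normalization (camera adjusted p = 0.0407, and 0.82 with an estimated correlation). The p53 targets were higher in 21 and lower in 14 of 37, with a median of 0.18, a mean of -0.08 and a test directed up (camera adjusted p = 0.819). Fas was lower at 1.25 ± 0.198 against 24.8 ± 0.637 RPKM and Lpin1 at 0.754 ± 0.0358 against 12.1 ± 0.117 RPKM, while Gls2 was higher at 4.62 ± 0.209 against 0.514 ± 0.0562 RPKM. Of the 5 cationic amino acid transporters 3 were higher and 2 lower, with a median of 0.36, a mean of -0.81 and a test directed down (camera adjusted p = 0.973), and Slc7a2 was at 1.62 ± 0.0659 against 129 ± 0.678 RPKM. Glutamine and glutamate metabolism genes were higher in 12 and lower in 9 of 23 (camera adjusted p = 0.829). The glutamine synthetase gene Glul was at 1.22 ± 0.0710 against 18.4 ± 0.570 RPKM and Asns at 175 ± 1.02 against 77.6 ± 0.454 RPKM. In all, 10418 genes passed, 5546 higher and 4872 lower in p53-null cells, and 2294 differed at least 2-fold, 1047 up and 1247 down, against 1615 up and 1315 down with the libraries rescaled to one sum. The median of all genes was 0.05 and became 0.16 with the libraries rescaled to one sum, and no list call in complete medium held with an estimated correlation.

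In glutamine-free medium the p53-null line stood below the WT line in the integrated stress response and above it in mitotic genes, though neither list call held with an estimated correlation. Integrated stress response genes were lower in p53-null cells in 32 of 35, median log2 difference -0.75 (camera adjusted p = 9.51e-08, and 0.097 with an estimated correlation). Cth was at 4.64 ± 0.439 against 106 ± 0.805 RPKM and Slc7a11 at 6.57 ± 0.270 against 38.0 ± 1.01 RPKM. Mitotic genes were higher in 26 of 30, median 0.75 (camera adjusted p = 4.5e-04, and 0.097 with an estimated correlation). Bub1 was at 40.6 ± 0.784 against 11.8 ± 0.259 RPKM and Aurka at 35 ± 0.142 against 11.7 ± 0.202 RPKM. Of the 5 cationic amino acid transporters 4 were lower in p53-null cells (camera adjusted p = 0.0332, and 0.25 with an estimated correlation). Slc7a2 was at 1.46 ± 0.0775 against 224 ± 1.70 RPKM, Slc7a3 at 0.459 ± 0.0730 against 6.63 ± 0.412 RPKM and Slc7a1 at 65.7 ± 0.618 against 90.1 ± 0.980 RPKM. Other amino acid transporters were lower in 13 of 20 (camera adjusted p = 0.0157, and 0.097 with an estimated correlation). Slc16a10 was at 0.397 ± 0.0174 against 4.88 ± 0.0787 RPKM and Slc6a15 at 12.1 ± 0.203 RPKM in WT and listed at 0 in p53-null cells. Glutamine and glutamate metabolism genes were lower in 16 of 23 (camera adjusted p = 0.0157, and 0.33 with an estimated correlation). Glul was at 2.13 ± 0.0771 against 10.5 ± 0.398 RPKM, Prodh at 0.331 ± 0.0188 against 3.70 ± 0.153 RPKM and Gls2, higher, at 3.94 ± 0.0717 against 0.468 ± 0.0567 RPKM. Cholesterol synthesis genes were lower in 17 and higher in 7 of 24 (camera adjusted p = 0.0429, and 0.33 with an estimated correlation). Idi1 was at 6.47 ± 0.246 against 24.7 ± 1.14 RPKM and Ebp, higher, at 17.3 ± 0.307 against 5.15 ± 0.379 RPKM. NRF2 targets were lower in 13 of 20 (camera adjusted p = 0.019, and 0.33 with an estimated correlation). Nqo1 was at 1.66 ± 0.153 against 33.9 ± 1.01 RPKM. Ribosomal protein genes were lower in 29 of 36, median -0.45, and 0.02 with quantile normalization (camera adjusted p = 1.81e-05, and 0.36 with an estimated correlation). Histone genes were lower in 6 of 9 (camera adjusted p = 0.0429, and 0.22 with an estimated correlation). Rn45s was at 2291 ± 387 against 3931 ± 144 RPKM. The p53 targets were higher in 19 and lower in 17 of 37, with a median of 0.20, -0.03 with quantile normalization, a mean of -0.12 and a test directed down (camera adjusted p = 0.743), and Cdkn1a, Fas (0.350 ± 0.0702 against 7.63 ± 0.166 RPKM) and Eda2r (0.0311 ± 0.00620 against 3.93 ± 0.0990 RPKM) were among those lower. Ccng1 (22.4 ± 0.205 against 8.05 ± 0.248 RPKM) and Mdm2 (18.3 ± 0.409 against 12.5 ± 0.298 RPKM) were among those higher.

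The 8 genes raised most in p53-null cells in glutamine-free medium were Krt18 (75.5 ± 1.31 RPKM), Peg3 (41.3 ± 0.444), Msln (64.5 ± 1.05), Efemp1 (33.9 ± 0.810, listed at 0 in WT), Grb10 (27.7 ± 0.524), the laminin gene Lama5 (34.9 ± 0.402), Gas6 (25.4 ± 0.333) and thymosin beta 4 (Tmsb4x, 588 ± 5.99, a gene with pseudogenes that may share its reads). The 8 lowered most, with their WT levels, were Enpp2 (198 ± 0.177 RPKM), Ptx3 (376 ± 5.04), Slc7a2, Erdr1 (63.5 ± 1.83), Serpine2 (58.8 ± 1.32), Rgs2 (51.0 ± 0.718), Dcn (216 ± 2.80) and the iron-binding lipocalin gene Lcn2 (88.8 ± 1.73). Erdr1 and Rgs2 were listed at 0 in the 3 p53-null libraries. The sums of RPKM were 315328 to 319735 in WT and 284426 to 288184 in p53-null libraries. In all, 10474 genes passed, 5890 higher and 4584 lower in p53-null cells, against 5002 higher and 5397 lower with median centring. The median of all genes, 0.11, became 0.26 with the libraries rescaled to one sum and -0.03 with median centring. Of the genes that passed, 2130 differed at least 2-fold, 57.6% of them higher, against 68% with rescaled libraries, 48.6% with quantile normalization and 44.5% with median centring, and no list call in glutamine-free medium held with an estimated correlation. Over the 5 comparisons, the lists of p53 targets, arginine and polyamine metabolism, amino acid sensing and mTORC1, autophagy and lysosome, and muscle and neural markers passed the list test in none.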

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

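These results are gathered here because the change on glutamine withdrawal differed between the 2 lines by the test of the difference itself, the WT response minus the p53-null response in limma. That test was planned, while the tests of explanations and the counts of splits in this part were chosen after the result was seen. Of 98 genes taken from those named for Trp53, Slc7a3, withdrawal or the difference, 96 differed. The same test called 9727 of all 11461 tested genes, 84.9%, so that count does not set the named genes apart. Many of the 98 were also chosen for a large change or for the difference itself. The log2 differences above 0, a larger rise or smaller fall in WT, were Car6 6.01, Avil 5.80, Cdsn 4.32, Angptl6 3.78, Trib3 3.23, Cox6a2 3.20, Atf5 3.11, Itgb7 3.10, Slc7a3 3.09, Cxcl15 3.07, Tspan8 3.05, Gsta1 3.05, Cth 3.01, Cd74 2.37, Atf3 2.33, Pycr1 2.15, Wars 2.07, Slc7a11 2.06, Ppp1r15a 2.02, Hmox1 2.00, Tars 1.73, Gpt2 1.72, Gadd45a 1.72, Ptn 1.71, Cdkn1a 1.71, Anxa8 1.70, Snhg12 1.60, Asns 1.42, Gsta4 1.41, Slc7a1 1.37, Nme1 1.30, Nqo1 1.28, Fosl1 1.17, Zfas1 1.15, Hist1h2bc 1.14, Nars 1.13, Cd68 1.07, Hk2 1.05, Krt19 0.95, Dcn 0.93, Idh3g 0.92, Ccl2 0.91, E2f2 0.91, Myc 0.91, Slc7a2 0.88, Snhg1 0.82, Plk2 0.74, Umps 0.72, Trp53 0.67, Hspa5 0.51, Cdc6 0.46, Nupr1 0.36, Prim1 0.34, Mdm2 0.13 and Slc7a6 0.068. Those below 0 were Gstt1 -4.22, Steap4 -4.20, Galnt15 -3.75, Ccdc80 -3.70, Nos2 -3.68, Col1a1 -3.63, Fabp4 -3.63, Ang2 -3.58, Mgp -3.46, Prelp -3.18, Col11a1 -3.15, Txnip -3.12, Thbs1 -3.08, Cbr2 -2.88, Mvd -2.75, Stmn2 -2.74, Col6a3 -2.70, Ifit1 -2.65, Olfml3 -2.61, Egr1 -2.54, Fdps -2.49, Cenpf -2.17, Ccnb2 -2.03, Isg15 -1.96, Dcxr -1.87, Sesn1 -1.80, Psrc1 -1.67, Stat2 -1.46, Lox -1.40, Plk1 -1.40, Maff -1.32, Plcxd2 -1.27, Tpi1 -1.27, Insig1 -1.21, Pfkm -1.20, Cdc20 -1.07, Aldoa -0.94, Ctps2 -0.72, Gstm1 -0.51, Idh1 -0.26 and Acta2 -0.17. With a pseudocount of 0.1 Ptn became -0.101, and with quantile normalization Acta2 became 0.072. Ang2, Fabp4, Galnt15, Gstt1, Nos2, Steap4 and Stmn2 averaged under 0.1 RPKM in both p53-null groups, and Cxcl15 and Tspan8 did in both WT groups, so for these the difference shows the change in the other line alone. Gsta1 and Krt19 were near that level in WT.

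By camera, which tests a list against the other genes, 12 gene lists differed at the preset correlation. Some of them share members, so these are not 12 separate results. Of these 12 calls 6 held with an estimated correlation, those of the integrated stress response, aminoacyl-tRNA synthetase, mitotic, cholesterol synthesis, matrix and interferon lists. Among the 12, the medians above 0 were those of integrated stress response genes (1.49), arginine and cationic amino acid transporters (0.88), aminoacyl-tRNA synthetases (0.86), NRF2 targets (0.61), glutamine and glutamate metabolism (0.55), nucleotide synthesis (0.38) and ribosomal protein genes (0.29, and 0.04 with quantile normalization). Below 0 were extracellular matrix (-1.71), cholesterol synthesis (-1.44), interferon response (-1.12, and -2.00 with a pseudocount of 0.1), mitotic (-1.05) and glycolysis genes (-0.29, and -0.19 with median centring).

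The integrated stress response list changed less in the p53-null line, and a higher level in complete medium could by itself leave less room to rise. Against that as the whole account, the list stood lower in the p53-null line without glutamine, by a median log2 difference of -0.75, with 32 of 35 members called lower, although that list call was lost with an estimated correlation (camera adjusted p = 0.097). Scaling or the pseudocount does not account for it either, since the lowest median difference of the responses over 4 other scalings was 1.43. A smaller response of all genes in that line stays open. The slope of the p53-null on the WT response was 0.295 for the list and 0.282 for the other 11426 genes. The 95% bootstrap interval for the list was 0.222 to 0.369 over 10000 resamples of its members, which are not independent. A slope also falls where the 2 lines disagree (Pearson r = 0.571 across all tested genes), so like slopes do not show a like reduction in size. The median absolute log2 change of called genes was 0.581 in WT and 0.329 in p53-null cells, and the list medians were 2.08 and 0.47. Loss of p53 is the biological explanation the design names, and with 1 line per genotype it is untested against any other difference between the lines.

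For the number of genes called in each pairwise comparison, the 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real splits gave 10321, 9403, 10418 and 10474 genes and the highest other split gave 0 in each. Each other split mixes libraries of the 2 groups compared, which puts the difference between the groups into the residual. The low counts of the other splits therefore say nothing about whether the calls arose by chance. For the difference of the responses, 1 of the 100 splits drawn, the real one, gave as many genes as the 9727 found, and the highest other gave 5466. Those splits mix the 2 lines within a medium, which puts the difference between the lines into the residual, so they do not test the difference of the responses.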

How the results depend on the processing

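Every alternative used here was planned. Of the alternative values of the counts of genes and of the Slc7a3 difference, 247 stayed within 1.5 times or on the same side of the threshold and 2 did not: the 379 genes changed at least 2-fold in p53-null cells became 745 with a pseudocount of 0.1 and 609 with libraries rescaled to one sum, and the cause was not tested. The Slc7a3 difference ranged from 3.06 to 5.29, and the genes changed on withdrawal from 9146 to 12334 in WT and from 8501 to 10695 in p53-null cells. The replicate numbers showed no pairing of the samples: deviations of same-numbered libraries correlated at -0.106 to 0.056, and 3 of 12 libraries matched their own number best. The spread within groups was near that of counting, so paired samples could also give correlations this low. These values therefore cannot decide whether the samples were paired. With the replicate number as a block the counts were 10322 and 9385 on withdrawal in WT and p53-null cells, 10409 and 10486 between lines in complete and glutamine-free medium, and 9733 for the difference of the responses, the Slc7a3 difference was 3.09, and no named gene or list gained or lost a call. Of the named genes' alternatives 8643 kept direction and side, 14 lost the call, 4 gained it and 7 changed sign, and Pqlc2, 1 of these genes, is not named elsewhere. The Rn45s change on withdrawal became 0 in WT and 0.127 in p53-null cells with quantile normalization. The other signs changed were of differences of the responses, Acta2 at 0.072 with quantile normalization (range -0.355 to 0.072), Ptn at -0.101 with a pseudocount of 0.1 (-0.101 to 1.91) and Mcm10 at 0.009 with that pseudocount, 0.086 with median centring and -0.025 to 0.004 when leaving out 1 library in turn. Of the lists' alternatives 1995 kept both, 56 lost the call, 37 of them with an estimated correlation, 3 gained it and 16 changed direction. The other losses were 11 with quantile normalization, 3 with median centring, 3 without the filter, 1 with a pseudocount of 0.1 and 1 on leaving out 1 library. The lists that lost a call in these ways are not named here. The 16 are adjusted p-values. Without the filter they were autophagy in WT 0.991 (range of its alternatives 0.606 to 0.992), p53 targets in p53-null 0.87 (0.709 to 0.989) and other amino acid transporters in complete medium 0.882 (0.882 to 0.998). With quantile normalization they were mTORC1 0.957 (0.0818 to 0.957) and ribosomal proteins 0.341 (2.56e-07 to 0.341) in p53-null, NRF2 targets 0.969 (0.935 to 0.988) and ribosomal proteins 0.967 (0.0161 to 0.967) in complete medium, and tricarboxylic acid cycle 0.935 (0.716 to 0.935) in glutamine-free medium. With median centring they were muscle and neural markers 0.779 in p53-null (0.757 to 0.999), cationic transporters 0.998 in complete medium (0.935 to 0.999) and autophagy 0.96 for the difference (0.705 to 0.967), and with a pseudocount of 0.1 histones 0.917 for the difference (0.0809 to 0.917). Leaving out 1 library turned autophagy in WT (0.916 to 0.992 over all) and muscle and neural markers in p53-null (0.959 to 0.995). The cause was not tested for any of the 16. What depth limits was not tested, since too few values were whole reads for the planned test.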

Other observations

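All tests in this part, the list of small nucleolar RNA (snoRNA) host genes and the genes named were chosen after values were seen. Noncoding host genes carry snoRNAs in their introns, and their spliced RNAs are mostly degraded during translation. Of these, in WT cells Snhg1 went from 72.2 ± 0.829 to 663 ± 0.106 RPKM, Zfas1 from 43.5 ± 0.903 to 432 ± 6.31 RPKM and Snhg12 from 25.3 ± 0.431 to 314 ± 5.78 RPKM (mean ± SD, n = 3). Gas5, the host gene first known from growth-arrested cells, went from 48.8 ± 1.27 to 99.5 ± 1.8 RPKM in WT and from 41.6 ± 0.131 to 46.8 ± 0.991 RPKM in p53-null cells. Snhg15 rose from 5.64 ± 0.670 to 51.0 ± 2.22 RPKM and Snhg5 from 32.1 ± 0.604 to 147 ± 0.321 RPKM in WT, while Snhg18 fell from 21.5 ± 0.844 to 2.38 ± 0.0532 RPKM. Vegfa, which encodes a growth factor for blood vessels, rose from 22.8 ± 0.147 to 115 ± 1.43 RPKM in WT and from 73.5 ± 0.974 to 90.5 ± 0.882 RPKM in p53-null cells, and the Cdkn2a locus, whose products p16 and ARF act upstream of RB and p53 by inhibiting CDK4, CDK6 and MDM2, fell from 108 ± 1.17 to 40.0 ± 1.71 RPKM in WT and from 82.9 ± 1.30 to 51.6 ± 1.43 RPKM in p53-null cells.

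Some imprinted genes, which are expressed from one parental copy, also differed between the lines, in both directions. Besides Peg3 and Grb10, the p53-null line had more Igf2 (26.8 ± 0.277 against 0.155 ± 0.0176 RPKM in complete medium, p53-null against WT), Impact (54.1 ± 0.608 against 2.38 ± 0.0610) and Mcts2 (21.6 ± 0.564 against 4.41 ± 0.807), and less Slc38a4 (9.37 ± 0.136 against 32.1 ± 0.370), Igf2r (12.5 ± 0.0994 against 22.6 ± 0.234) and Sgce (6.15 ± 0.376 against 15.5 ± 0.557). These genes were picked by their values, so they test nothing about imprinted genes as a class. Xist was present in both lines, at 267 ± 1.32 against 128 ± 0.718 RPKM in complete medium, and the Y-linked genes Ddx3y and Uty averaged at most 0.00358 RPKM in any group. In glutamine-free medium Xist did not differ between the lines, at 288.4 ± 3.45 against 288.2 ± 6.08 RPKM (limma adjusted p = 0.95).

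One hypothesis is that snoRNA host genes rise together on withdrawal, tested on the host genes left after Snhg1, Snhg12 and Zfas1, which had shown the pattern. In WT cells 11 of 16 rose and 3 fell, median log2 change 0.84, and the camera p of 0.019 was 0.063 with an estimated correlation, so a shared rise may hold there at the preset correlation. In p53-null cells 7 rose and 6 fell, median 0.03, and the camera p of 0.89 leaves the question open. The difference between the lines had a median of 0.77 (camera p = 6e-04, and p = 0.013 with an estimated correlation). The sign of the p53-null median changed with scaling (-0.07 to 0.06), while the medians in WT (0.82 to 0.98) and of the difference (0.76 to 0.87) did not.

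In complete medium the p53 target list was not mostly lower in the p53-null line, with 21 members higher and 14 lower of 37. In glutamine-free medium it was divided, 19 higher and 17 lower, and its median of 0.20 became -0.03 with quantile normalization, with up to 18 members lower over 4 other scalings. In complete medium a shift of all genes between the lines could hide a fall of the list, but the most members called lower under any of 4 other scalings was 14. An exchange of the 2 lines' labels would put Trp53 higher in the libraries labelled p53-null, and Trp53 was lower there by a log2 difference of -1.0 in complete medium. What stays open is that WT cells in complete medium may have little active p53, which was not tested, and that the deposited values do not show which exons of Trp53 were read.

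Krt18 at 59.6 ± 0.665 RPKM, Krt19 at 17.5 ± 0.404 RPKM and Msln at 149 ± 0.75 RPKM in the p53-null line in complete medium could come from epithelial cells mixed into the cultures. The 7 epithelial genes Epcam, Cdh1, Cldn3, Cldn4, Cldn7, Esrp1 and Ocln argue against epithelial cells that express them, since the highest stood at 0.15% of Krt18. Of the keratins that pair with Krt18 and Krt19, Krt8 was at 0.763 ± 0.0573 RPKM and Krt7 at 0.712 ± 0.0812 RPKM. Wt1 (7.65 ± 0.149 RPKM) and Upk3b (4.79 ± 0.304 RPKM) were measured in the same libraries, so the line may have mesothelial features, a hypothesis from markers that were seen first. It leaves the low levels of Krt8, Krt7 and the mesothelial marker Lrrn4 (0.593 ± 0.0426 RPKM) unexplained. The markers also did not move together on withdrawal. Krt18 rose to 75.5 ± 1.31 RPKM, while Krt19, Msln, Wt1 and Upk3b fell, Upk3b to 1.29 ± 0.162 RPKM. Mesothelial cells mixed into the cultures were not tested for and stay open. Whether the expression of these markers goes with the loss of p53 or with another difference between the 2 lines cannot be told apart with 1 line per genotype.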
